A study of Mus musculus with 6 samples.

How the data were processed

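RNA from whole testes of Dnmt3L knockout mice and control littermates was sequenced at 16.5dpc (days post coitum), 10dpp and 20dpp (days post partum). The labels give a C57BL/6 background, TRIzol extraction of total RNA and a stranded Illumina TruSeq mRNA library kit. Each of the 6 libraries is a pool, of 7 or 8 mice at 16.5dpc and of 3 mice at the later ages, and there is 1 library per genotype and age. The labels call the controls heterozygous at 16.5dpc and 10dpp and wild type at 20dpp, so the genotype of the control differs with age.

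The deposited values are estimated counts of reads per repeat family, 1 value for each family in each library, and they need not be whole. Between 7.91% and 13.5% of the values in a library were whole within 1e-06. Only families with a value above 0 are listed. Reads were aligned with Bowtie to the mouse build mm9, per the submitters' processing notes. The versions, the repeat annotation, the rule that shared a read between families and the use of strand are not given in the sources used here. A family's value sums over its copies in the genome, so no copy and no coordinate can be assigned, and near-identical subfamilies can exchange reads. Reads from copies that lie within gene transcripts cannot be separated from transcripts of the elements themselves. Sense and antisense reads cannot be told apart. The files hold no gene rows, so the Dnmt3L transcript, which would check the labels, and the markers of testis cell types could not be read. The supplied reference genome is of another build and was not used.

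The listed counts sum to 2035033 in the 16.5dpc control, 1548394 in the 16.5dpc knockout, 2275706 in the 10dpp control, 1671536 in the 10dpp knockout, 8639952 in the 20dpp control and 11239673 in the 20dpp knockout. These are totals of repeat reads, not of the whole libraries, and the 20dpp totals are 3.80 to 7.26 times the others. Counts were scaled to CPM (of the listed counts) with TMM factors, which ranged from 0.900 in the 20dpp knockout to 1.07 in the 16.5dpc control. For each age the log2 ratio of knockout to control was taken after adding 0.5 counts, over families with at least 50 counts in both libraries together. Counts were rounded for the exact Clopper-Pearson interval (95%) of each ratio, conditional on the sum of both counts, which was carried over to the scaled ratio. These intervals cover counting error only, and reads shared between families are not independent. With 1 library per group a ratio compares 2 libraries and has no replicate check, so no p-value is given for a single age. A ratio of at least 2-fold serves as a description of size. For shares of the listed counts, exact Clopper-Pearson binomial intervals were used.

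Families were grouped by name patterns of repeat entries into 14 lists, of which 12 had members: young LINE-1 (A, T and Gf subfamilies), older LINE-1, IAP, ETn/MusD, MMERVK10C with RLTR10 LTRs, other ERVK, ERV1, MERVL with related class III entries, MaLR, B1/B2 and related SINEs, MIR with LINE-2, and DNA transposons. The lists of satellites and of structural RNAs had 0 members, and 273 of the 787 families belong to no list. A list therefore need not match the whole class it is named after, and its median and counts describe the list only. After the names were seen, 2 entries (L1MDa and MER50) were kept out of the lists whose patterns could take them. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean level in 10 bins, as a description of the libraries compared.

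The genotype effect averaged over the ages was tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) on the rounded counts of all 6 libraries, with age as a block, the default expression filter and Benjamini-Hochberg adjustment at 0.05. The 2 residual degrees of freedom hold the differences of the effect between ages as well as the noise between libraries. The standard error of an averaged log2 change was obtained from the estimate and its F value. That F value uses a variance moderated across families, so the standard error is not the family's own spread over the ages. On simulated counts for the 730 families tested, with 200 families changed, this test called 93% of 2-fold and 98% of 4-fold changes when noise between libraries was drawn at the fitted dispersion of 0.0336. Of its calls, 3.54% were unchanged families, and it made 0 calls when nothing was changed. These simulations held the same effect at each age and the same dispersion for every family, so these shares need not hold for the real libraries. The exact interval held the true ratio in 95.3% of simulated pairs of independent Poisson counts. These pairs had no shared reads and no noise between libraries, so this checks the calculation only.

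Families named for an age are the 10 with the highest and the 5 with the lowest ratio among those past the minimum whose interval excludes 0. In addition 13 entries are always named: IAPEz-int, IAPEY3-int, L1Md_A, L1Md_T, L1Md_Gf, L1Md_F2, MMERVK10C-int, ETnERV2-int, MERVL-int, MMVL30-int, MuLV-int, B1_Mm and B2_Mm2. For the averaged test the rule took the 10 smallest adjusted p-values past the threshold in each direction. The lists, this rule, the tests and the alternatives were set before the data were examined, except where stated. Families named outside the rule were chosen after their values were seen, and the text says so.

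Alternatives were scaling on the total of the listed counts, DESeq2 1.42.0 size factors, scaling on the DNA transposon and MIR/LINE-2 families, no minimum or a minimum of 200 counts, and pseudocounts of 0.05 and 5. For the averaged effect they were the same scalings, the DESeq2 Wald test, limma 3.58.1 on log2 values, no age block, no filter, and leaving out the pair of libraries of each age in turn. Thinning of the 20dpp libraries was added after the data were seen.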

Results

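Repeat-derived RNA was measured in 6 pooled libraries of whole mouse testis, 1 from Dnmt3L knockout animals and 1 from control littermates at each of 3 ages. Dnmt3L is a catalytically inactive cofactor of the de novo DNA methyltransferases and is needed for methylation of retrotransposons in male germ cells. Germ cells at 16.5dpc are arrested prospermatogonia in the period of de novo methylation. In normal testes the first spermatocytes are entering meiosis at 10dpp, and pachytene spermatocytes are abundant at 20dpp. Whether the knockout testes held these cells could not be read here. The files list 787 repeat families, 762 of them in all 6 libraries. The 25 families missing from at least 1 library reach at most 20 counts in any library. The listed repeat counts total 1548394 to 11239673 per library, and the comparison asked which transposon families differ between the genotypes and at which age.

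At 16.5dpc most families in 4 lists of long terminal repeat (LTR) retrotransposons, IAP, ERV1, ETn/MusD and MMERVK10C, were higher in the knockout library, while the young LINE-1 subfamilies lay close to the control. IAPEz-int, the internal sequence of the intracisternal A-particle retrotransposon, was at 6927 CPM in the control and 11979 CPM in the knockout library, a ratio of 1.73 (95% counting interval 1.69 to 1.77). MMERGLN-int, a gammaretrovirus-like (ERV1) element, was 2.41-fold higher (2.3 to 2.53), and MMVL30-int, the internal sequence of the VL30 retrotransposons, 1.71-fold higher (1.65 to 1.77). L1Md_T, an active LINE-1 subfamily, was at 12331 CPM in the control and 14361 CPM in the knockout library, a ratio of 1.16 (1.14 to 1.19).

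All 16 measured IAP families had log2 ratios above 0 at 16.5dpc, under every scaling tried, and 15 of them had intervals above 0. Their median was 0.61, at the 100th percentile of random lists matched on level. At least 2-fold higher were IAPLTR4_I (2.25-fold, 1.69 to 3.01), IAPLTR4 (2.24-fold, 1.79 to 2.78) and IAPLTR3-int (2.05-fold, 1.81 to 2.32), the last chosen after its value was seen. IAPEY3-int, the most abundant IAP internal entry after IAPEz-int, was 1.76-fold higher (1.70 to 1.83). Of the 23 ERV1 families 16 had intervals above 0 and 1 below, with a median log2 ratio of 0.40 (percentile 100). MuLV-int, from murine leukaemia virus sequences, was 1.63-fold higher (1.53 to 1.74). The 5 ETn/MusD families all had intervals above 0, with a median of 0.50 (percentile 99.5), and ETnERV2-int was 1.41-fold higher (1.35 to 1.47). Of the 9 MMERVK10C and RLTR10 families 7 had intervals above 0 (median 0.31, percentile 98.2), and MMERVK10C-int was 1.53-fold higher (1.46 to 1.6). The other ERVK list (108 families, median 0.06) and the MaLR list (89 families, median 0.05) stayed near 0 and turned to -0.06 and -0.07 when scaled on total counts. The MERVL list (10 families, median 0.05) likewise turned to -0.07, and MERVL-int had a log2 ratio of -0.05 (-0.12 to 0.01).

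The 3 young LINE-1 subfamilies had log2 ratios of 0.15 (L1Md_A), 0.22 (L1Md_T) and 0.26 (L1Md_Gf) at 16.5dpc, with a median at percentile 89.2. Older LINE-1 families lay the other way. Of 96 measured, 71 had intervals below 0 and 7 above, and their median of -0.34 was at percentile 0 of the matched lists. The abundant older subfamily L1Md_F2 was near 0 at this age (log2 ratio 0.00, -0.02 to 0.03), and its sign turned under total scaling. DNA transposons, relics of cut-and-paste elements, had a median of -0.14 over 85 families (percentile 2.38), and the ancient MIR and LINE-2 families had a median of 0.21 over 12 (percentile 97.2). Among SINEs, B1_Mm was 1.39-fold higher (1.37 to 1.42) and B2_Mm2 1.16-fold higher (1.15 to 1.18). The median of the 27 B1/B2 and related SINE families was 0.10 (percentile 60.4), and -0.01 when scaled on total counts.

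Over all 678 families compared at 16.5dpc, 18 were at least 2-fold higher and 2 at least 2-fold lower in the knockout library. Of the 18, 12 remained with a minimum of 200 counts. LTR81B was 5.12-fold higher (3.74 to 7.28, from 48 and 174 counts), MER50 was 4.15-fold higher (2.53 to 7.28, from 21 and 62 counts) and LTR88a 3.06-fold higher (1.87 to 5.25). FordPrefect, a DNA element outside the lists, with 1404 counts in the control and 2876 in the knockout library, was 2.92-fold higher (2.74 to 3.12). LTR48B (2.75-fold), MamGypLTR2 (2.65-fold) and Alu (2.62-fold) completed the 10 highest. The lowest were L1MEg2, 2.18-fold higher in the control (1.29 to 4.0), and LTR86A1, 2.05-fold higher in the control (1.1 to 4.29), followed by Charlie7a, Charlie21a and RLTR20A1 with log2 ratios of -0.87, -0.87 and -0.85. Neither of the 2 families at least 2-fold lower reached 200 counts in both libraries together.

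At 10dpp IAPLTR1_Mm and IAPEz-int had the highest ratios, and young LINE-1 RNA was still close to the control. IAPEz-int was at 5664 CPM in the control and 16139 CPM in the knockout library, a ratio of 2.85 (2.79 to 2.91). Its LTR, IAPLTR1_Mm, was 3.19-fold higher (3.0 to 3.40). L1Md_T was at 9629 CPM in the control and 10531 CPM in the knockout library, a ratio of 1.09 (1.07 to 1.12). L1Md_A had a ratio of 1.17 (1.14 to 1.20), and for L1Md_Gf a difference was not detectable at this depth (1.06, 0.957 to 1.18).

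Of the 16 IAP families 8 had intervals above 0 at 10dpp and 1, IAPEy-int, below. The median log2 ratio was 0.36 (percentile 100). IAPLTR2_Mm (2.24-fold, 2.08 to 2.41) and IAPLTR2a (2.04-fold, 1.78 to 2.35) joined IAPEz-int and IAPLTR1_Mm among the families at least 2-fold higher. IAPEY3-int had a ratio of 1.43 (1.38 to 1.49). MMERVK10C-int was 1.79-fold higher (1.72 to 1.87), and its list had a median of 0.30 (percentile 99.8) with 5 of 9 intervals above 0 and 2 below. The ERV1 median was 0.17 (percentile 99.8), with 9 of 23 intervals above 0 and 1 below, and the ETn/MusD median 0.17 (percentile 98.1). MMVL30-int was 1.46-fold higher (1.42 to 1.5), ETnERV2-int 1.34-fold (1.29 to 1.41) and MuLV-int 1.25-fold (1.16 to 1.33). MERVL families lay slightly below the control, with 7 of 10 intervals below 0, a median of -0.12 (percentile 0.52) and a log2 ratio of -0.12 (-0.18 to -0.06) for MERVL-int.

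Median log2 ratios at 10dpp were 0.00 for older LINE-1 (percentile 71.2), -0.02 for other ERVK (percentile 0.93), -0.06 for MaLR (percentile 0), 0.00 for B1/B2 SINEs (percentile 63.5), 0.10 for MIR and LINE-2 (percentile 99.02) and 0.08 for DNA transposons (percentile 99.6). Scaling on total counts gave older LINE-1 and B1/B2 SINE medians below 0. L1Md_F2, B1_Mm and B2_Mm2 had log2 ratios of 0.02, 0.05 and 0.05, all of which turned sign under at least 1 scaling. Of 678 families, 7 were at least 2-fold higher and 0 at least 2-fold lower. Besides the IAP entries these were Tigger16a, a DNA transposon (2.32-fold, 2.08 to 2.59), MER67D (2.25-fold, 1.43 to 3.69) and MER34B-int (2.02-fold, 1.88 to 2.18). RLTR45-int (log2 ratio 0.96), MER73 (0.93) and LTR45 (0.91) followed. The lowest ratios were those of L1M3d (-0.99), FLAM_A (-0.70), L1M3de (-0.70), FordPrefect (-0.70, -0.81 to -0.58) and LTR16E2 (-0.61).

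At 20dpp young LINE-1 RNA stood well above the control, IAPEz-int and MMERVK10C-int were higher, and 44 families, among them IAPLTR3 and LTR68, were at least 2-fold lower in the knockout library. L1Md_T was at 9613 CPM in the control and 41217 CPM in the knockout library, a ratio of 4.29 (4.26 to 4.32). L1Md_Gf was 3.16-fold higher (3.06 to 3.27) and L1Md_A 2.86-fold higher (2.83 to 2.89). IAPEz-int was 3.46-fold higher (3.44 to 3.49), at 7982 CPM in the control and 27654 CPM in the knockout library. IAPLTR3, an IAP LTR, went the other way, at 550.0 CPM in the control and 29.6 CPM in the knockout library, which is 18.6-fold higher in the control (16.6 to 21.0).

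**Figure D1:**
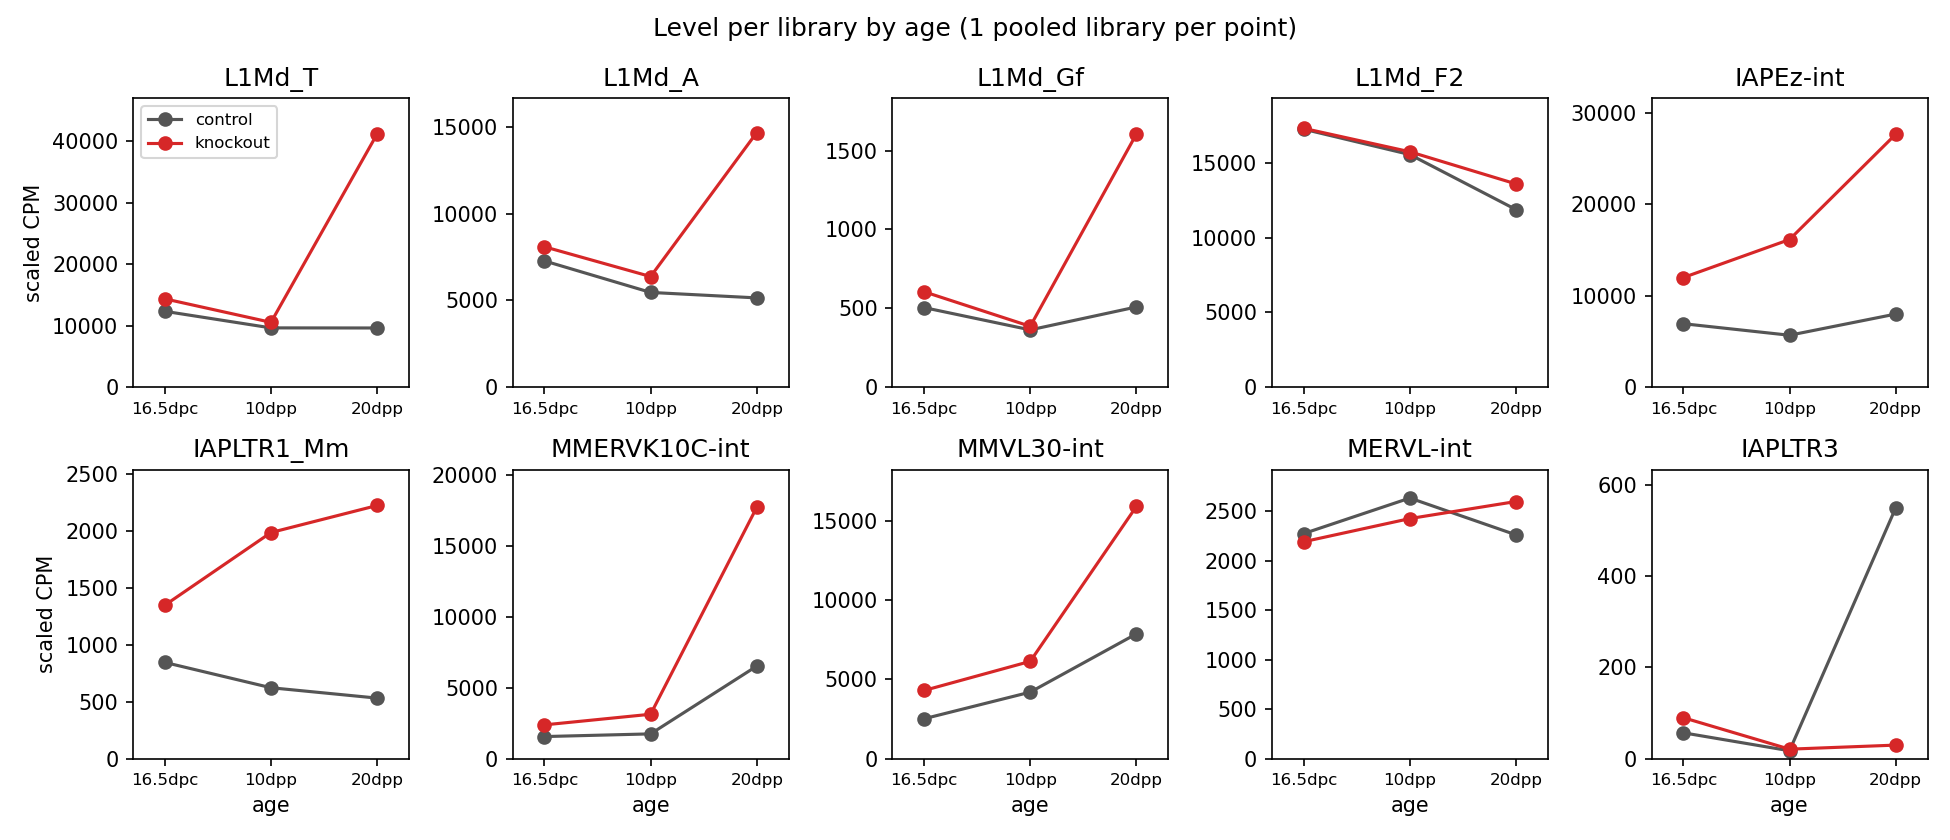
Scaled CPM (y axis, linear, from 0) of 10 repeat families at the 3 ages (x axis), with 1 pooled library per point, controls in grey and knockouts in red; lines only join the ages. L1Md_T reads 9613 CPM in the 20dpp control and 41217 CPM in the 20dpp knockout, IAPEz-int is higher in the knockout library at each age, and IAPLTR3 is high only in the 20dpp control.

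The 3 young LINE-1 subfamilies had a median log2 ratio of 1.66 at 20dpp (percentile 99.9) and made up 5.18% of the listed counts in the knockout library (exact binomial interval 5.16 to 5.19), against 1.56% in the control (1.55 to 1.57). At 16.5dpc these shares were 2.27% and 2.15%, and at 10dpp 1.74% and 1.58%. The older L1Md_F2 had a ratio of 1.14 (1.14 to 1.15) at 20dpp. The 98 older LINE-1 families had a median of 0.00 (percentile 13.2), or -0.18 under total scaling, and spread both ways, with 38 intervals above 0 and 36 below. At least 2-fold lower were L1M3a (log2 ratio -1.73) and Lx2A1 (-1.51), both chosen after their values were seen.

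IAP families diverged at 20dpp. Of 16, 11 had intervals above 0 and 4 below, and the median was 0.43 (percentile 99.98) with a range from -4.21 to 2.07. IAPLTR1_Mm was 4.18-fold higher in the knockout library (4.06 to 4.32) and IAPEY3-int 1.55-fold higher (1.53 to 1.57). IAPLTR3-int, chosen after its value was seen, was 2.48-fold higher in the control (2.44 to 2.53). As a group IAP took 3.70% of the listed counts in the knockout library (3.69 to 3.71) and 2.01% in the control (2.0 to 2.02). In the MMERVK10C list MMERVK10C-int was 2.72-fold higher (2.69 to 2.74) and its LTR RLTR10C 2.69-fold higher (2.61 to 2.78). The median of the 9 families was 0.25 (percentile 97.4). Among ERV1 families MMVL30-int was 2.02-fold higher (2.0 to 2.04) and MuLV-int 1.44-fold (1.40 to 1.47), whereas MuRRS-int, chosen after its value was seen, was 2.31-fold higher in the control (2.21 to 2.42). The ERV1 median was -0.06 (percentile 13.5) with 9 intervals above 0 and 11 below, while the summed counts of the list gave a log2 ratio of 0.57. ETn/MusD families had a median of -0.21 (percentile 3.35), and a log2 ratio of 0.09 for their summed counts. ETnERV2-int was at 0.04 (0.02 to 0.06), and at -0.14 under total scaling.

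The other ERVK list had a median of -0.11 at 20dpp (percentile 0.10), with 57 of 109 intervals below 0 and 32 above. Its 7 families at least 2-fold lower included RLTR9A2 (4.71-fold higher in the control, 4.15 to 5.36), RodERV21-int (4.54-fold, 4.37 to 4.71) and RLTR13D6 (3.93-fold, 3.76 to 4.11), all named after their values were seen. MaLR had a median of -0.06 (percentile 5.10) and MERVL of -0.02 (percentile 33.0), with a log2 ratio of 0.20 (0.17 to 0.23) for MERVL-int. B1/B2 SINEs had a median of 0.14 (percentile 81.2), MIR and LINE-2 of 0.17 (percentile 90.4) and DNA transposons of 0.12 (percentile 98.9). These 3 medians turned to -0.04, -0.02 and -0.07 under total scaling. B2_Mm2 had a log2 ratio of 0.20 (0.19 to 0.21), and B1_Mm of 0.18 (0.16 to 0.19), which became -0.01 under total scaling.

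Over the 742 families compared at 20dpp, 15 were at least 2-fold higher and 44 at least 2-fold lower in the knockout library, or 9 and 56 when scaled on total counts. Besides the families above, the highest included Charlie10b (2.35-fold, 1.33 to 4.56, from 16 and 44 counts), MLT1F1-int (2.28-fold, 1.59 to 3.38) and MER47A (2.26-fold, 2.02 to 2.53). After IAPLTR3 the lowest were LTR68, 16.2-fold higher in the control (13.5 to 19.5), MER52-int, 11.2-fold (9.57 to 13.2), LTR28, 8.68-fold (5.20 to 16.5), and MER90a, 5.20-fold (4.8 to 5.65). Of the 44 lower families 24 belong to no list, 7 to other ERVK and 4 to MaLR, and the rest to the DNA transposon (3), IAP (2), older LINE-1 (2), ERV1 (1) and MERVL (1) lists. Those in the smaller groups that have not been named were MLT1H2-int (log2 ratio -2.36), MLT1J-int (-1.34), MLT1I-int (-1.31), MLT1J1-int (-1.26), Kanga11a (-1.80), Charlie11 (-1.40), Kanga1 (-1.21) and ERVL-E-int (-1.32), chosen after their values were seen. Because the lists follow name patterns, the 24 families in no list can still belong to the classes that the lists are named after.

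**Figure D2:**
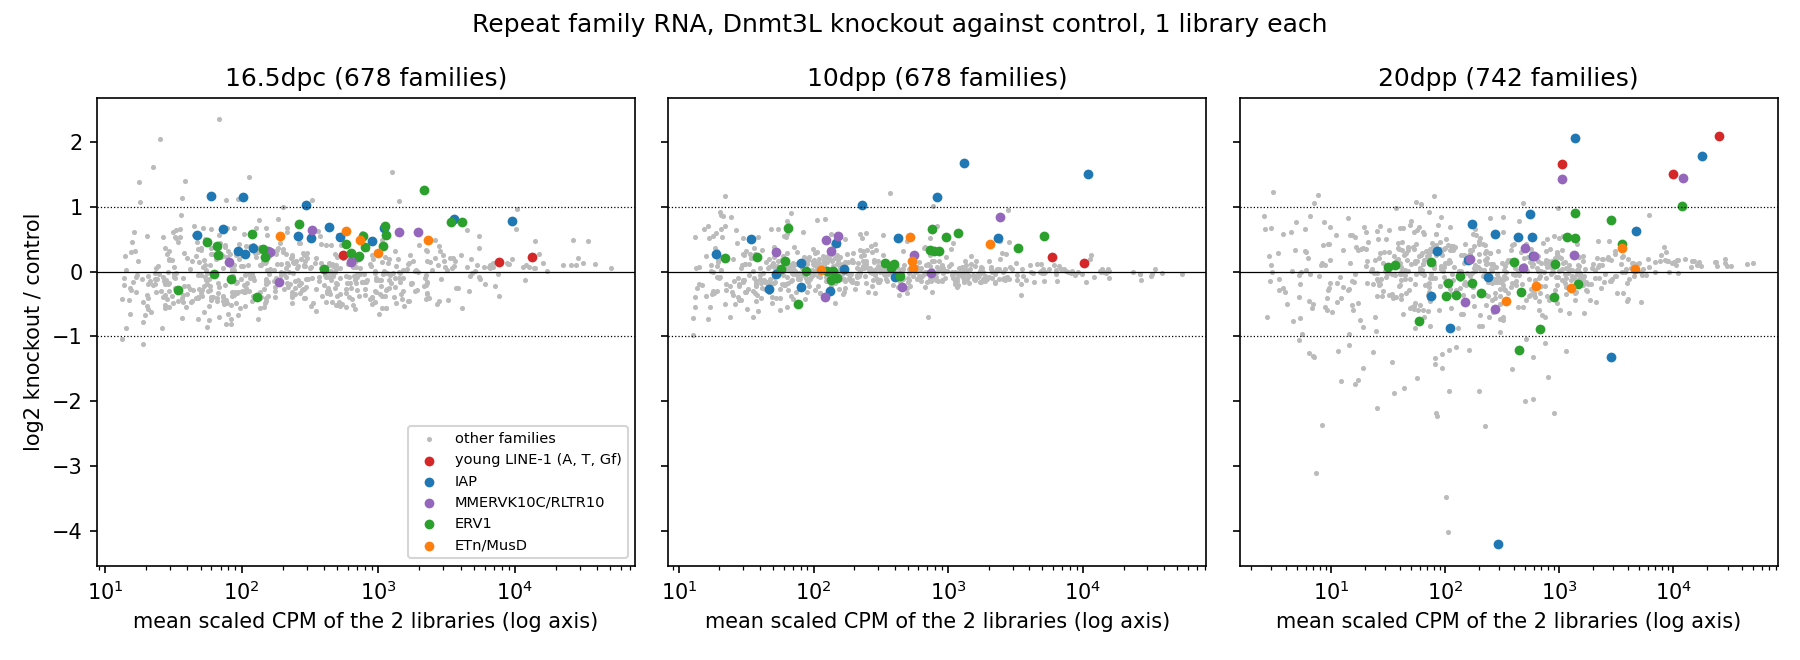
Log2 ratio of knockout to control (y axis) against the mean scaled CPM of both libraries (x axis, log scale) for each repeat family past the minimum count at each age, with 1 pooled library per genotype; colours mark 5 lists and dotted lines mark 2-fold. Young LINE-1 families lie between 0.09 and 0.26 at the first 2 ages and between 1.51 and 2.10 at 20dpp, where 44 families lie at or below the lower dotted line.

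**Figure D3:**
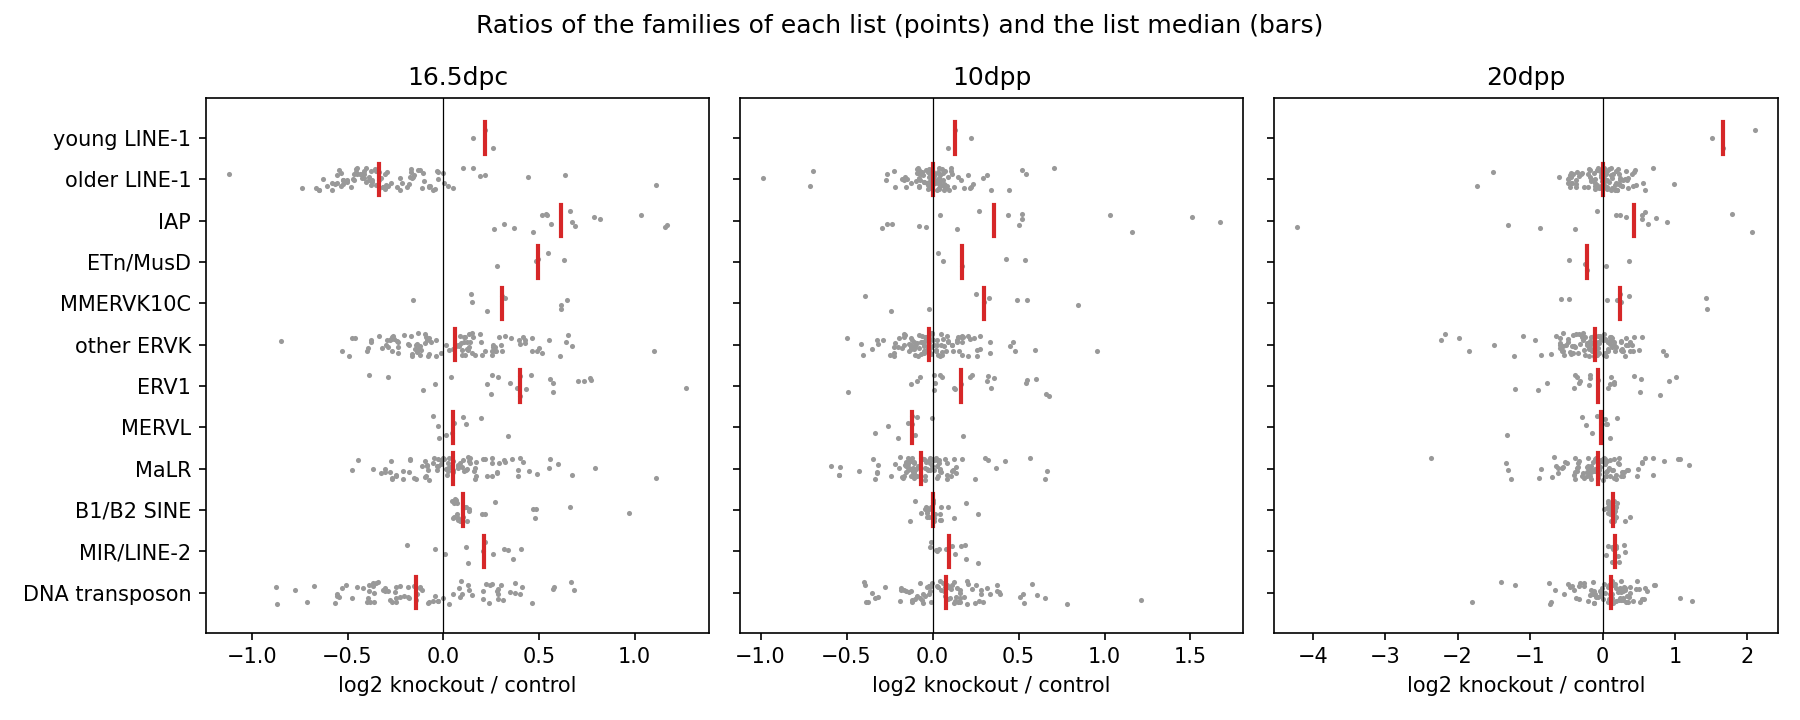
Log2 ratio of knockout to control (x axis, with its own range at each age) for the families of 12 lists (rows), with 1 point per family and a red bar at the list median. The older LINE-1 median is -0.34 at 16.5dpc, and the IAP medians are 0.61, 0.36 and 0.43 from the youngest age to the oldest.

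The ages were compared through the differences of these log2 ratios, which have no test here. The 20dpp ratio exceeded the 10dpp ratio by 1.97 for L1Md_T, 1.57 for L1Md_Gf and 1.29 for L1Md_A, and by 0.28 for IAPEz-int and 0.60 for MMERVK10C-int. IAPEz-int had log2 ratios of 0.79, 1.51 and 1.79 in order of age, and L1Md_T of 0.22, 0.13 and 2.10. Across the 672 families measured at every age, Spearman's rho between the ratios was 0.11 for 16.5dpc and 10dpp, 0.29 for 10dpp and 20dpp and 0.07 for 16.5dpc and 20dpp. Pearson's r was 0.14, 0.30 and 0.07. These are correlations across families, which are not independent replicates, and each age has its own control library. The libraries are of whole testis and no cell type marker could be read. Neither a ratio at a single age nor its change with age can therefore be told apart from a difference in cell composition.

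In the controls the ETn/MusD, MMERVK10C, IAP and ERV1 lists had medians above 0 at 20dpp against 10dpp, and the young LINE-1 median was near 0. The ETn/MusD list had a median log2 ratio of 1.45 between these ages, MMERVK10C of 0.72, IAP of 0.62 and ERV1 of 0.57, against 0.00 for young LINE-1 and -0.32 for older LINE-1. MMERVK10C-int was at 1742 CPM in the 10dpp control and 6523 CPM in the 20dpp control, and IAPLTR3 at 17.2 and 550.0 CPM. The remaining list medians were 0.34 for MIR and LINE-2, 0.17 for MERVL, 0.13 for other ERVK, 0.09 for DNA transposons, 0.05 for B1/B2 SINEs and -0.09 for MaLR. Of 728 families, 72 were at least 2-fold higher and 29 at least 2-fold lower at 20dpp. From 16.5dpc to 10dpp, 3 of 687 were at least 2-fold higher (RNERVK23-int, RLTR9B and Charlie21a) and 5 lower (IAPLTR3, RLTR44A, RLTR10A, MER52-int and Arthur1A), named after their values were seen. The young LINE-1 median between these ages was -0.41 and the IAP median -0.31. In the knockouts, 54 of 722 families were at least 2-fold higher and 29 lower at 20dpp than at 10dpp. The list medians were 1.97 for young LINE-1, 1.03 for ETn/MusD, 1.0 for MMERVK10C, 0.64 for IAP, 0.27 for ERV1 and -0.30 for older LINE-1. For the remaining lists in the knockouts they were 0.37 for MIR and LINE-2, 0.31 for MERVL, 0.19 for B1/B2 SINEs, 0.13 for DNA transposons, -0.01 for other ERVK and -0.09 for MaLR. The control at 20dpp is labelled wild type and the earlier controls heterozygous, and each age is 1 library. The labels give no sequencing batch and the 20dpp totals are 3.80 to 7.26 times the others, so a difference between ages cannot be told apart from one between sequencing runs.

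IAPEz-int, IAPLTR1_Mm, MMERVK10C-int and MMVL30-int were higher in the knockout library at each age, but for the genotype effect averaged over the 3 ages 0 of 730 families passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment over all families (smallest adjusted p = 0.143). IAPEz-int had an averaged log2 change of 1.37 ± 0.19 (SE), IAPLTR1_Mm of 1.48 ± 0.27, MMERVK10C-int of 0.97 ± 0.17 and MMVL30-int of 0.78 ± 0.11. Each had a ratio above 1 at 3 of 3 ages. The SE is moderated across families and does not give a family's own spread over the ages. At an unadjusted p under 0.05 there were 67 families, 53 higher and 14 lower, where 36.5 would be expected by chance. The edgeR p-values were also adjusted over each list alone, without adjustment for the number of lists. In this way 5 of 16 IAP families passed as higher (IAPEz-int, IAPEY3-int, IAPLTR1_Mm, IAPLTR1a_Mm and IAPLTR4_I). So did 6 of 23 ERV1 families (MMVL30-int, RLTR6_Mm, RLTR4_Mm, MMERGLN-int, RLTR4_MM-int and MuLV-int). Adjusted over the list alone, 1 of 5 ETn/MusD families (ETnERV3-int) and 1 of 9 in the MMERVK10C list (MMERVK10C-int) also passed as higher. In the other 8 lists with members 0 families passed. Young LINE-1 had averaged log2 changes of 0.80 ± 0.40 for L1Md_T, 0.68 ± 0.32 for L1Md_Gf and 0.63 ± 0.28 for L1Md_A, which were 0.18, 0.18 and 0.19 without the 20dpp pair. The smallest p adjusted over the young LINE-1 list alone by edgeR was 0.097.

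For the remaining always-named families the averaged log2 changes were 0.66 ± 0.10 (IAPEY3-int), 0.52 ± 0.12 (MuLV-int), 0.32 ± 0.12 (ETnERV2-int), 0.24 ± 0.11 (B1_Mm), 0.16 ± 0.08 (B2_Mm2), 0.08 ± 0.08 (L1Md_F2) and 0.01 ± 0.10 (MERVL-int). The last pair turned sign under total scaling. Leaving out the 16.5dpc pair put the averaged log2 change of B1_Mm at 0.11. The averaged log2 change of L1Md_F2 was 0.12 without the 10dpp pair and 0.01 without the 20dpp pair. The averaged log2 change of MERVL-int was 0.04, 0.09 and -0.08 without the 16.5dpc, 10dpp and 20dpp pair in turn. DESeq2's Wald test with the same design gave 17 families higher and 0 lower, among them IAPEz-int, MMERVK10C-int and MMVL30-int and no young LINE-1, and limma gave 0. Without the 16.5dpc pair edgeR called 2 families, IAPEz-int and IAPLTR1_Mm. Adjusted over the list alone, IAP calls numbered 4 without the 16.5dpc pair, 0 without the 10dpp pair and 8 without the 20dpp pair, and ERV1 calls 3, 2 and 6.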

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

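The tests of background and of scaling for older LINE-1 at 16.5dpc were chosen after the result was seen, and thinning of the 20dpp libraries was added to the alternatives after the data were seen. The families singled out below met a rule of opposite direction: at least 1.5-fold higher in the knockout library at one age and at least 1.5-fold lower at another, with both counting intervals excluding 0. The rule was applied only to the families named by rule, so other families can meet it too. IAPLTR3-int, named above after its value was seen, is such a family by its ratios at 16.5dpc and 20dpp. The differences were not tested, because each group is 1 library.

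IAPLTR3 had a log2 ratio of 0.66 at 16.5dpc and of -4.21 at 20dpp, a difference of -4.88. MER50 went from 2.05 to -0.92 between the same ages, a difference of -2.97. FordPrefect had a log2 ratio of 1.55 at 16.5dpc, -0.70 at 10dpp and -1.84 at 20dpp, so that the later ratios differed from the first by -2.24 and -3.39.

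At 20dpp 59 families were at least 2-fold apart, against 7 at 10dpp, and 44 of the 59 were lower in the knockout library. Depth as the whole cause is argued against, because thinning the 20dpp libraries to the 10dpp totals left a median of 52.5 families apart over 100 draws (46 to 61). Scaling moved by the abundant higher families would place unchanged families below 0, but the DNA transposon and MIR/LINE-2 medians were 0.12 and 0.17. Scaling on these families gave 48 lower families. This argues against scaling as the cause only if these reference families did not change themselves. A candidate explanation is cells that appear between 10dpp and 20dpp in the control and are fewer in the knockout. RNA of the lower families would come from these cells, either from the elements or from gene transcripts that hold copies. The median log2 ratio of the 20dpp to the 10dpp control over the lower families was 1.55 (quartiles 1.04 to 2.08), with 42 of 44 above 0. In the knockouts it was -0.06. The 20dpp control enters both ratios and is the control labelled wild type, so a deviation of that library alone stays open, and no gene row is at hand to read cell types.

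At 16.5dpc 71 of 96 older LINE-1 families had counting intervals below 0 and 7 above, and the list median log2 ratio was -0.34. More unspliced or genomic background in the control library would lower other ancient repeats too. The MIR and LINE-2 median was 0.21 (bootstrap interval 0.06 to 0.33) and that of MaLR 0.05, but that of DNA transposons was -0.14. Because these lists went different ways, they do not decide on background. Scaling on DNA transposon and MIR/LINE-2 families alone gave a median of -0.28 for older LINE-1 (bootstrap interval -0.33 to -0.24), so it stayed below 0. This scaling was chosen after the result was seen, and its reference lists themselves went different ways. It therefore does not decide on scaling moved by abundant families. The bootstrap intervals given here resample families within 1 pair of libraries, so they hold no spread between libraries. An effect of genotype stays open and untested with 1 library per group. Background in the control library stays open as well, as does a difference between the libraries in the base composition of the repeats they captured.

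The averaged test called 0 of 730 families. With 0 calls in the real grouping, each of the 10 splits of the 6 libraries into 3 and 3 gives at least as many (10 of 10), so the count decides nothing, and with 10 splits no share under 0.05 can be reached. The highest of the other splits had 26 calls. Both splits with 26 calls keep the 16.5dpc libraries in one arm and the 10dpp libraries in the other, so that the age block takes up that contrast and the calls come from the 20dpp pair alone.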

How the results depend on the processing

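Thinning of the 20dpp libraries was the alternative chosen after the data were seen. Total scaling moved the median log2 ratio of all families by -0.12 at 16.5dpc and by -0.18 at 20dpp, and ratios at those ages shift by as much. The families at least 2-fold apart at 20dpp numbered 9 higher and 56 lower under total scaling (13.8% higher, against 25.4%), and 14 higher and 38 lower in the median after thinning. Without a minimum count there were 44 higher and 13 lower at 16.5dpc, 13 higher and 26 lower at 10dpp and 23 higher and 54 lower at 20dpp, since sparse families then enter. Lower families at 16.5dpc numbered 1 when scaled on DNA transposon and MIR/LINE-2 families, and 0 with a minimum of 200 counts or a pseudocount of 5. At 10dpp there was 1 lower family under total scaling (6 higher), 1 under scaling on DNA transposons and MIR/LINE-2 (5 higher), and 1 with a pseudocount of 0.05. The DNA transposon median at 20dpp was -0.0682 under total scaling, against 0.12. In the controls, 9 families were at least 2-fold lower at 10dpp than at 16.5dpc under total scaling, against 5. Where scaling changed a count, the cause is the shift it makes in every ratio.

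The averaged effect gave 17 higher families with the DESeq2 Wald test, whose p-values assume no uncertainty in the dispersion, and 93 of its adjusted p-values were not given. With edgeR the count was 0 under 3 other scalings, without the age block and without the filter, and it ranged from 0 to 2 when the pair of 1 age was left out. Adjusted over the list alone, IAP calls ranged from 0 to 8 and ERV1 calls from 2 to 6 over those left-out pairs; without the age block they were 2 and 0. The cause of these changes was not tested. The age block pairs the control and knockout library of each age, and the labels give no replicate numbers for another pairing. Of the other values, 75 counts that answer a comparison stayed within 1.5 times. A list median has no interval of its own, so its limit was the median distance from centre to end of its families' counting intervals. Named families and list medians kept their sign and stayed within their interval or limit, or on their side of the threshold where tested, in 779 cases. In 10 more the sign turned about a value near 0. They moved beyond their interval or limit in 115 cases, with the sign turned in 14. Tests of single named families passed the threshold under an alternative in 6. The alternative without satellite and structural RNA families was not run, as none is listed, and pseudocounts for normalized values did not apply. The 16.5dpc and 10dpp libraries hold the fewest counts, which limits the ratios of sparse families such as MER50 or L1MEg2 there.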

Other observations

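The families in these paragraphs were chosen after their values were seen. At 16.5dpc 5 SINE families had the highest ratios of their list, whose median log2 ratio was 0.10. B2_Mm1a was at 7036 CPM in the control and 13771 CPM in the knockout library, a ratio of 1.96 (95% counting interval 1.92 to 2.0), and B2_Mm1t had a ratio of 1.58 (1.55 to 1.62). B1_Mus2 (1.40), B1_Mm (1.39) and B1_Mus1 (1.38) followed, while the remaining families of the list had log2 ratios between 0.05 and 0.27. At 10dpp B2_Mm1a and B2_Mm1t had ratios of 1.20 (1.18 to 1.22) and 1.15 (1.12 to 1.17), and at 20dpp of 1.30 (1.29 to 1.32) and 1.24 (1.23 to 1.25), in each case the highest of the list. The averaged log2 change of B2_Mm1a was 0.54 ± 0.15 (SE), higher at 3 of 3 ages, and did not pass in edgeR (adjusted p = 0.434, and 0.206 adjusted over the list alone). RNERVK23-int, a class II endogenous retrovirus, was 2.14-fold higher at 16.5dpc (2.02 to 2.27), 1.39-fold at 10dpp (1.34 to 1.45) and 1.84-fold at 20dpp (1.82 to 1.87).

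Families that were more abundant in the 20dpp than in the 10dpp control went different ways in the knockout. RLTR10B had a 20dpp to 10dpp ratio of 11.6 in the controls and 11.1 in the knockouts, and ETnERV3-int of 7.37 and 6.57. IAPLTR3 had ratios of 31.6 and 1.41, LTR68 of 32.3 and 1.35, and MER52-int of 12.1 and 0.714. IAPLTR3-int lay between, with 24.6 and 9.62. Of the 72 families at least 2-fold higher in the 20dpp control, 53 had a log2 ratio of knockout to control below 0 at 20dpp and 34 were at least 2-fold lower, with a median of -0.81. The 20dpp control library enters both ratios, which by itself favours this order. Families at least 2-fold higher in the 20dpp knockout had a median log2 ratio of 20dpp to 10dpp of 0.00 in the controls and 1.20 in the knockouts. Here the 20dpp knockout library enters both the choice of families and the ratio in the knockouts, which by itself favours the higher value.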
